A study of Caenorhabditis elegans with 9 samples.

How the data were processed

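DNase-seq libraries were made from nuclei of wild-type N2 animals, 4 embryo and 5 L1 arrest replicates, per the labels. Nuclei were digested at 0, 20, 40, 80, 120 or 160 U/mL DNase I for 3 minutes at 37 °C, and fragments under 500 bp were kept, per the labels' protocols. For each sample the level with the highest enrichment at enhancers of the lin-39 and ceh-13 region was sequenced, per the series design text. Reads were 50 bp in 3 embryo and 3 L1 replicates and 76 bp in 1 embryo and 2 L1 replicates, per the labels. Read length was therefore mixed within each stage, and its effect cannot be separated in merged lists. FastQC, Bowtie 1.0.0 and SAMtools and the ce10 genome are named in the submitters' processing notes, which give no settings.

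Peaks were called by the authors with HOTSPOT version 3 over 150 bp windows, filtered at an IDR level of 0.1, cleared of repeats and blacklisted regions and merged per stage, per the series design text. A region counted as exonic if 75% of it lay in an exon of the WormBase WS241 gene models, and promoters lay within 300 bp of a start codon, per the same text. Footprints were called by the authors with DNase2TF at an FDR of 0.05 over 6 to 40 bp, per the same text, and the deposited stage lists held widths of 6 to 30 bp. The peak and footprint lists carry a deposited score, whose scaling is not given in the sources used here. The DHS scores as deposited were whole multiples of 1/64, with no tolerance allowed, in 99.9% of entries, and scores were used to rank or filter within a list, never as levels between lists. In the closing section the sites open in both stages were also ranked among themselves in each stage. The motif tables carry a p-value per term or motif as deposited by the authors, and the tool and its adjustment are not given in the sources used here.

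The lists were checked before use. The numbers of DHS equal the 41825 and 23670 stated in the series design text. The embryo footprint list held 125825 entries with 8044 exact repeats, and the L1 list 79107 with 4771, so overlapping footprints were merged to 55890 and 32685. A score of minus infinity stood in 236 embryo and 372 L1 footprint entries, which were kept. The gene tables give WormBase identifiers and sequence names. These were matched to protein-coding genes of the WBcel235 gene table, which was used only for names and for which genes neighbour each other. Of 11053 embryo genes 10471 matched a coding gene (94.7%), and of 8202 L1 genes 7760 (94.6%). The rest were pseudogenes, noncoding RNA genes or names without a match (185 embryo and 142 L1), and they did not enter the gene comparisons.

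All coordinates are in ce10 and count from 1. Overlap meant at least 1 bp. Chance overlap came from 1000 circular shifts of 1 list along each chromosome, and for footprints within the intervals open in both stages. Shares carry exact binomial intervals at 95%, which cover counting error only. Groups of DHS or genes were compared with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment within each family of tests, at a threshold of 0.05. For the stage shift of a gene list, 100000 random draws of genes matched for their number of DHS were used. Mantel-Haenszel odds ratios compared groups within quintiles of score, bins of 25 bp of width or groups of position. The adjusted values of gene lists are adjusted over the 34 lists. Neighbouring genes can share a DHS, and DHS are not independent of each other, so these p-values treat as separate what may be linked.

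The 34 gene lists, the main tests and most alternatives were fixed before the data were examined, and later additions are named as such. Genes were named by a rule fixed at the same time. It takes lin-39 and ceh-13, the 10 genes with most noncoding DHS in each stage, the 10 largest differences in each direction and the 10 genes with most arrest-associated DHS. It also takes up to 4 members of each list past the threshold and the 10 best entries of each motif table, with ties in alphabetical order. Genes known only by a clone name were skipped, which left 4 unnamed ahead of the first gene with more L1 than embryo DHS. Some of the genes taken are left out for brevity. Raw reads were not used here. The replicate letters are not shared between stages, so no pairing exists. Alternatives changed the overlap, the list length, the score limit, the gene assignment, the counting of neighbours and the location filter.

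The tests were tried on simulated data. Lists were drawn from all 19971 coding genes, so only their members with a DHS entered the stage shift and arrest-associated comparisons. DHS were simulated as independent, without linked neighbours. The simulations adjusted over fewer lists and used fewer random draws than the tests on the data. Their recovery shares therefore need not hold for the data. For the stage shift over 10821 genes, lists of 100 genes with a planted odds ratio of 2 were recovered in 100% of 20 simulations, and lists of 30 genes in 60%. The lists called by stage shift had odds ratios of 1.21 to 1.54 or, for ceh genes, 0.800, without matching for the number of DHS. Such weaker shifts were not simulated. For the presence of a DHS over 19971 genes the shares were 80% and 15%. For arrest-associated genes over 7760 genes they were 25% and 5%, so smaller lists had little power in that comparison. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.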

Results

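Open chromatin was mapped by DNase-seq in wild-type Caenorhabditis elegans of the N2 strain at 2 stages. In this assay DNase I cleaves accessible DNA in isolated nuclei, and the short fragments it frees are sequenced. Embryos at around 40 cells gave 4 replicates (A to D), and larvae held in L1 arrest, the state of newly hatched larvae kept without food, gave 5 replicates (V to Z). The lists used here hold DNase I hypersensitive sites (DHS), their noncoding parts, footprints (short protected stretches inside DHS) and the genes assigned to them, with 1 merged list per stage. No test between replicates can be made from merged lists, so no p-value below is set against the spread between animals or cultures. The number of reads behind each site is not given in the lists.

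The embryo list held 41825 DHS and the L1 list 23670, or 1.77 embryo DHS for each L1 DHS. They covered 6.28 Mb in the embryo and 3.55 Mb in L1. The median width was 150 bp in each list, and 66 embryo and 31 L1 DHS were wider than 150 bp. No DHS overlapped another of its own list. A part outside exons remained for 26034 embryo DHS (62.2%, exact 95% binomial interval 61.8 to 62.7%) and for 15826 L1 DHS (66.9%, 66.3 to 67.5%). The L1 share was higher by 4.62 percentage points (two-sided Fisher's exact test, odds ratio 1.22, p = 2.37e-32). Among the few DHS of at least 200 bp the difference was 5.24 points and did not pass the test (p = 0.655, Fisher's exact test).

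The comparison of the stages asks which regulatory sites are open in both and which in 1 stage alone. Of the 23670 L1 DHS, 21770 (92.0%, 91.6 to 92.3%) overlapped an embryo DHS by at least 1 bp, which is 7.30 times the mean for L1 DHS shifted along the chromosomes. Of the 41825 embryo DHS, 21777 (52.1%, 51.6 to 52.5%) overlapped an L1 DHS, against 7.13% after shifting. Each p was 0.001, the smallest that 1000 shifts can give. Overlap followed the deposited score in the embryo: 10.3% of the DHS in the lowest quintile by score overlapped an L1 DHS, and 95.8% of those in the highest quintile. In L1 the shares were 86.8% and 96.4%. With the embryo list reduced to the L1 number by score, 78.3% of L1 DHS overlapped an embryo DHS and 78.3% of embryo DHS an L1 DHS.

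**Figure D1:**
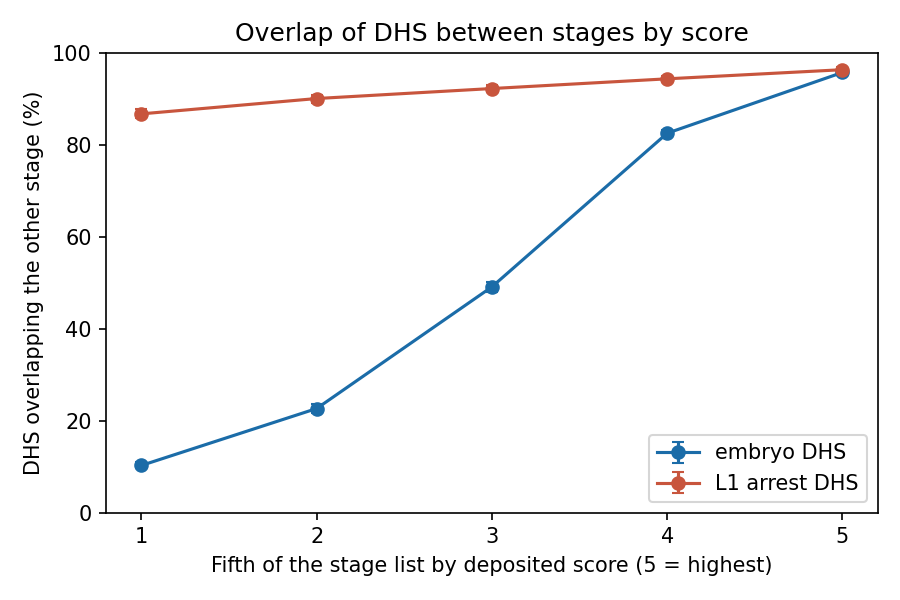
Share of DHS (%) that overlap a DHS of the other stage, by quintile of the stage's own deposited score, with exact 95% binomial intervals as bars. The embryo share goes from 10.3% to 95.8% and the L1 share from 86.8% to 96.4%.

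The L1-arrest-associated list held 1835 DHS, which is 11.4% (10.9 to 11.9%) of the 16084 L1 noncoding DHS. Each of them is an L1 noncoding DHS without an overlapping embryo noncoding DHS, and no other L1 noncoding DHS lacks such an overlap. An embryo DHS of any kind overlapped 219 of them (11.9%), and 606 (interval 30.9 to 35.2%) had an embryo DHS within 150 bp. The median deposited score was 188 for arrest-associated DHS and 219 for other L1 noncoding DHS. The arrest-associated share went from 18.8% in the lowest quintile of L1 noncoding DHS by score to 5.19% (4.45 to 6.02%) in the highest. No fed L1 larvae were sampled. The name of the list is the authors', and arrest cannot be told apart here from hatching, larval age or cell composition.

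In each direction, introns held more of the noncoding DHS without an overlap in the other stage's noncoding list than of those with one. Of the arrest-associated DHS, 49.2% (46.8 to 51.5%) lay in introns, against 39.3% of other L1 noncoding DHS (odds ratio 1.49, adjusted p = 4.79e-15, Fisher's exact test with Benjamini-Hochberg adjustment). Embryo DHS without an overlapping L1 noncoding DHS were 49.1% intronic and those with one 39.2% (odds ratio 1.49, adjusted p = 1.94e-58, Fisher's exact test), a split of the embryo list that was chosen after the data were seen. The shared DHS of both comparisons are the same sites, so the directions are not independent. Within quintiles of score the arrest-associated difference was 9.55 points. It was not compared within bins of width, while 32.1% of arrest-associated and 19.1% of other L1 noncoding DHS were under 150 bp. The comparison was also not repeated without the 219 arrest-associated DHS that overlapped an embryo DHS of any kind. Promoters were taken here as DHS outside introns and less than 300 bp from the assigned gene, on either side and not only at the start codon. They held 15.2% of arrest-associated and 19.3% of other L1 noncoding DHS (adjusted p = 2.84e-05, Fisher's exact test). The intergenic share was 35.6% against 41.5% (adjusted p = 2.41e-06, Fisher's exact test). Over the whole lists, introns held 43.8% of 26644 embryo and 40.4% of 16084 L1 noncoding DHS, 3.41 points fewer in L1 (-3.41 points, adjusted p = 1.05e-11, Fisher's exact test). Intergenic DHS made up 37.0% and 40.8% (adjusted p = 8.04e-15, Fisher's exact test). Promoter shares were 19.2% and 18.8% and the difference did not pass (-0.439 points, adjusted p = 0.269, Fisher's exact test), nor among DHS of at least 200 bp (adjusted p = 1), while it passed without X (-0.883 points, adjusted p = 0.0441). Among the 15 L1 and 19 embryo DHS of at least 200 bp the intron difference turned to 15.1 points and the intergenic one to -14.04, and neither passed (adjusted p = 1, Fisher's exact test).

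**Figure D2:**
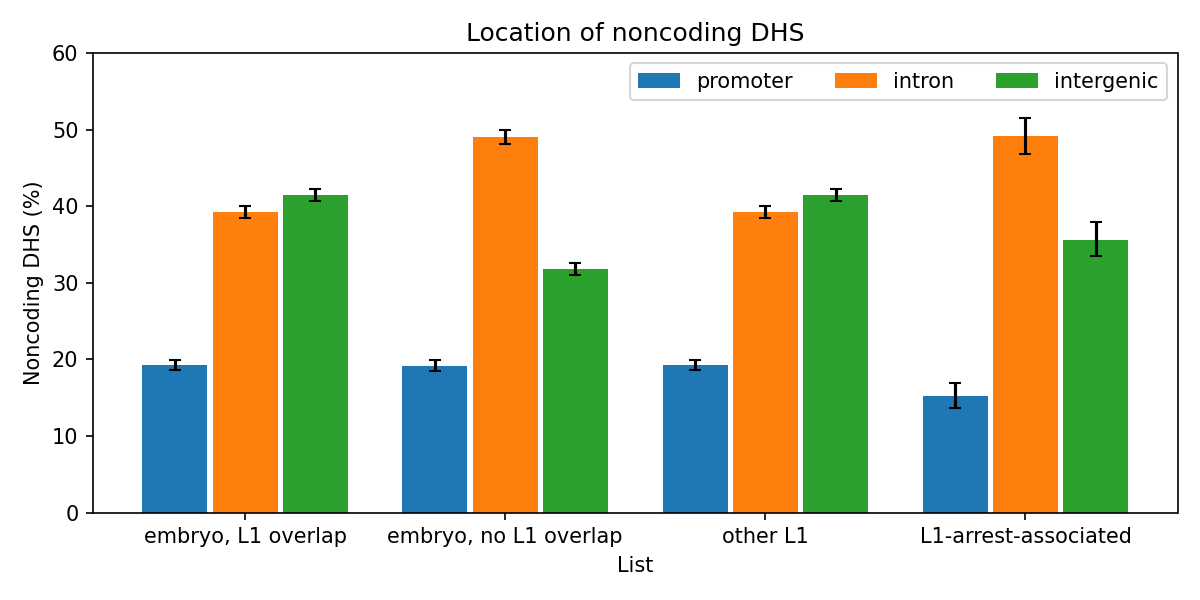
Share of noncoding DHS (%) in promoters, introns and intergenic sequence for embryo DHS with and without an overlapping L1 noncoding DHS, other L1 DHS and L1-arrest-associated DHS, with exact 95% binomial intervals as bars. Promoters are DHS outside introns less than 300 bp from either side of the assigned gene. Introns hold 49.1% and 49.2% of the DHS without an overlap in the other stage's noncoding list and 39.2% and 39.3% of those with one.

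The X chromosome held fewer arrest-associated DHS and chromosomes III and IV held more. X held 263 of 1835 arrest-associated DHS (14.3%) and 2800 of 14249 other L1 noncoding DHS (19.7%), an odds ratio of 0.684 (0.597 to 0.785, adjusted p = 1.28e-07, Fisher's exact test). Chromosome IV held 18.9% against 15.3% (odds ratio 1.29, adjusted p = 3.08e-04, Fisher's exact test) and chromosome III 331 of 1835 against 2135 of 14249 (odds ratio 1.25, adjusted p = 0.00167). Without the window of 66.1 kb on IV that held 35 arrest-associated DHS, a setting chosen after the data were seen, the IV difference went from 3.58 to 2.23 points (adjusted p = 0.0302, Fisher's exact test). Against all other L1 DHS, coding ones included, the X difference was -2.72 points in place of -5.32 (adjusted p = 0.00799, Fisher's exact test). The shares on I, II and V did not pass the test. The embryo list, split the same way after the data were seen, had another pattern. X held 20.5% of embryo DHS without and 19.7% with an L1 overlap, which did not pass (adjusted p = 0.172, Fisher's exact test). V held 15.6% against 18.8% (adjusted p = 4.47e-11) and II 18.3% against 16.7% (adjusted p = 0.00229, Fisher's exact test). Between the whole lists, V held 17.3% of embryo and 18.9% of L1 noncoding DHS (adjusted p = 2.93e-04, Fisher's exact test), while II held 4650 of 26644 and 2660 of 16084 (-0.914 points) and X 5342 and 3063 (-1.01 points, adjusted p = 0.0305 for each).

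**Figure D3:**
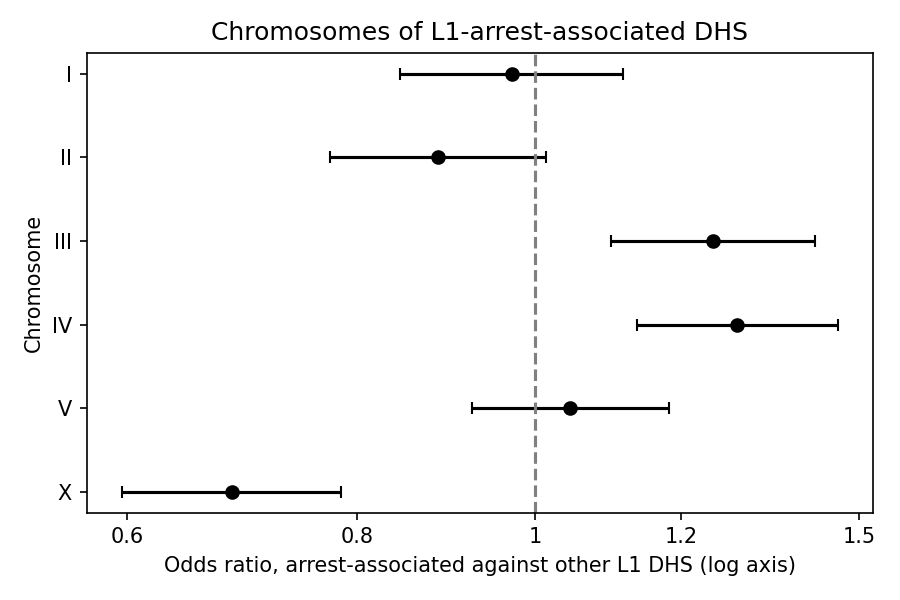
Odds ratio per chromosome (log axis) for L1-arrest-associated against other L1 noncoding DHS, with 95% intervals as bars and a dashed line at 1. X lies at 0.684, chromosome III at 1.25 and chromosome IV at 1.29.

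Footprints were found in 21857 of 26644 embryo noncoding DHS (82.0%, 81.6 to 82.5%) and in 13511 of 16084 L1 noncoding DHS (84.0%, 83.4 to 84.6%). The difference of 1.97 points (p = 1.63e-07, Fisher's exact test) turned its direction with DHS matched for width (-1.56 points, p = 1.11e-06 from the Mantel-Haenszel odds ratio) and among DHS open in both stages (-6.39 points, p = 1.62e-65). In those shared DHS 91.8% of embryo and 85.5% of L1 DHS held a footprint, so no direction is read from the whole lists. The shared DHS are the same sites in both lists, and Fisher's exact test ignored this pairing, so its p-value there is only a guide. After overlapping footprints were merged, an embryo DHS with any held 2.56 and an L1 DHS with any 2.42 on average. Arrest-associated DHS held a footprint in 72.8% of cases and other L1 noncoding DHS in 85.5% (-12.7 points, odds ratio 0.455, p = 3.83e-39, Fisher's exact test). More of the arrest-associated DHS were under 150 bp, at 32.1% against 19.1%. In comparisons chosen after the data were seen, the Mantel-Haenszel odds ratio was 0.606 (0.540 to 0.680) within quintiles of score and 0.787 (0.677 to 0.915) within bins of width. Within both its interval was 0.939 to 1.28 and the difference 0.510 points, so no lower footprint share is read beyond width and score.

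Footprints of the stages fell on the same bases more often than chance placement within the same DHS. Inside the 14256 intervals open in both stages, 81.1% of 25233 merged L1 footprints overlapped an embryo footprint, against 75.0% for footprints shifted within their interval. For 33380 embryo footprints the shares were 65.9% and 62.0%. With at least 50% reciprocal overlap, the L1 share was 49.4% against 24.6% and the embryo share 37.9% against 18.8%. Each p was 0.001, the smallest that 1000 shifts can give. The shifts kept neither the distance of a footprint from the centre of its interval nor the sequence under it. Shared protein binding is therefore not read from these shares.

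Genes were assigned to noncoding DHS by the authors' tables. Of 19971 protein-coding genes, 7410 had a noncoding DHS in both stages, 3061 in the embryo list alone and 350 in the L1 list alone. More embryo than L1 DHS were assigned to 6579 genes and more L1 than embryo DHS to 772. The largest embryo number was 37 at ptp-3, a LAR-type receptor tyrosine phosphatase, which had 18 in L1. The cadherin gene hmr-1 had 28 and 13, nhr-27, a nuclear hormone receptor gene, 28 and 13, and kcnl-1, a calcium-activated potassium channel gene, 28 and 23, the largest L1 number among genes with a symbol. The FOXO factor gene daf-16 had 24 embryo and 14 L1 DHS, and the potassium channel gene unc-103 had 24 and 16. The kinase genes dkf-2 and mbk-2 each had 23 and 14. In L1, zfh-2, a zinc finger homeobox gene, had 17 DHS, and unc-73, a Trio-like exchange factor gene, and gap-2, a Ras GTPase activator gene, had 15 each.

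Among genes with a symbol the widest gaps toward the embryo were at ptp-3 (37 against 18) and the teneurin gene ten-1 (21 against 4). hmr-1 and nhr-27 (28 against 13 each) and unc-53, which acts in cell migration (25 against 10), followed with the same gap. The numbers were 16 and 4 at swah-1, 20 and 9 at tir-1, 21 and 11 at ptb-1, and 16 and 6 at rin-1. These gaps were not scaled for the longer embryo list, which held 26644 noncoding DHS against 16084 in L1. Over all genes, L1 DHS made up 37.5% of the noncoding DHS of both stages. Toward L1 the gaps were small among genes with a symbol. ddl-3 had 0 embryo and 4 L1 DHS, and the hedgehog-related gene wrt-2 and the chemoreceptor genes srh-120 and srw-34 had 0 and 3 each. fbxa-63, rgs-8.2 and the potassium channel gene twk-46 had 2 and 5 each. The intestinal actin gene act-5 had 8 and 10. pqn-83 held 5 arrest-associated DHS, and clip-1, ddl-3, eps-8 and lag-1, the DNA-binding factor of Notch signalling, held 4 each. Single genes were not tested.

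Body wall muscle, axon guidance and pan-neuronal genes had noncoding DHS more often than other genes in each stage, and chemoreceptor, detoxification and C-type lectin genes less often. Of 34 gene lists fixed before the data were examined, 22 differed from other genes in the embryo (16 higher, 6 lower) and 17 in L1 (12 higher, 5 lower), by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. The test asked for any assigned DHS and was not matched for gene length, intron content or intergenic span. The authors' removal of repeats was not tested as a cause of low shares in gene families. Accessibility by tissue or function is therefore not read from these differences. All 28 body wall muscle genes had an embryo DHS, against 52.4% of other genes (adjusted p = 2.51e-07, Fisher's exact test), and 25 had an L1 DHS, against 38.8% (adjusted p = 4.88e-07). The titin-like gene ttn-1 had 13 embryo and 10 L1 DHS, unc-89 11 and 8, and unc-22 10 and 7. Axon guidance and adhesion genes had DHS in 45 of 51 cases in the embryo (88.2%, adjusted p = 1.27e-06, Fisher's exact test) and in 43 of 51 in L1 (84.3%, adjusted p = 7.09e-10). Among them mig-10 had 18 embryo and 10 L1 DHS. Pan-neuronal genes reached 22 of 26 in each stage (adjusted p = 0.00397 and 1.33e-05, Fisher's exact test), with unc-13 at 16 and 9 and unc-31 at 14 and 11. Neuron terminal identity factors stood at 31 of 35 in the embryo (adjusted p = 4.49e-05, Fisher's exact test) and 24 of 35 in L1 (adjusted p = 0.00142), with zag-1 at 11 and 7. Genes of EGF, Ras and FGF signalling stood at 19 of 21 in each stage (adjusted p = 0.00111 and 1.11e-05, Fisher's exact test), with lin-1 at 12 and 6. Heterochronic and molting regulators stood at 15 of 18 and 14 of 18 (adjusted p = 0.0186 and 0.00274, Fisher's exact test), with lin-14 at 20 embryo and 12 L1 DHS and daf-12 at 15 and 9. Starvation and energy metabolism regulators stood at 29 of 39 and 27 of 39 (adjusted p = 0.0148 and 8.13e-04, Fisher's exact test), with the CREB gene crh-1 at 13 DHS in each stage and hlh-30 at 14 and 11. Ion channel and neurotransmission genes stood at 128 and 102 of 181, Wnt pathway genes at 23 and 21 of 30, hypodermis and cuticle genes at 27 and 26 of 38, pharynx genes at 16 and 14 of 21 and early lineage factors at 22 and 19 of 30, and each passed in both stages. Of 4 further lists that passed in the embryo and not in L1, some differed from other genes by nearly as much in L1, and the stages were not tested against each other here. Hox genes stood at 6 of 6 and 5 of 6 (47.6 and 44.5 points above other genes, adjusted p = 0.04998 and 0.0656, Fisher's exact test). Cilia genes stood at 29 and 21 of 38 (23.9 and 16.44 points, L1 adjusted p = 0.0731, Fisher's exact test). Neuropeptide genes stood at 72 and 53 of 109 (13.7 and 9.82 points, L1 adjusted p = 0.0656, Fisher's exact test) and ceh homeobox genes at 43 and 30 of 64 (14.8 and 8.04 points, L1 adjusted p = 0.234). Notch pathway genes, nuclear hormone receptors and the insulin, TGF-beta and steroid dauer pathway passed in neither stage. In the embryo 4 of these higher lists no longer passed with 1 gene kept per neighbourhood, with differences of nearly the same size. These were hypodermis and cuticle genes (18.7 points before and 17.9 after), early lineage factors (20.9 and 20.01), ceh genes (14.8 and 14.3) and Hox genes (47.6 in each case). Neuropeptide genes in the embryo and pharynx genes in each stage did not pass when at least 2 DHS were asked of a gene. Calls were also gained in L1. There 18 lists passed with 1 gene kept per neighbourhood and 19 with at least 2 DHS, in each case 16 of them among the 17 called before.

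Chemoreceptor genes had an embryo DHS in 356 of 1307 cases (27.2%, against 54.2% of other genes, adjusted p = 7.97e-80, Fisher's exact test) and an L1 DHS in 272 (20.8% against 40.1%, adjusted p = 1.54e-45). Histone genes stood at 18 and 17 of 72 (adjusted p = 1.43e-05 and 0.0169, Fisher's exact test), detoxification genes at 63 and 49 of 185 (adjusted p = 4.19e-06 and 0.00143), and collagens at 65 and 42 of 156 (adjusted p = 0.0176 and 0.0053). C-type lectins stood at 95 and 62 of 239 (adjusted p = 3.67e-04 and 1.53e-04, Fisher's exact test). F-box genes passed in the embryo, at 140 of 322 (adjusted p = 0.00406, Fisher's exact test), and not in L1, at 107 of 322 (adjusted p = 0.0656), and the difference between the stages was not tested this way. With 1 gene kept per neighbourhood, the histone difference in the embryo shrank from -27.5 to -6.98 points and the F-box one from -9.10 to -4.30, and neither passed (adjusted p = 0.563 and 0.312, Fisher's exact test). The histone difference in L1 went from -15.3 to -2.50 points (adjusted p = 1, Fisher's exact test).

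Chemoreceptor, F-box, detoxification and histone genes had a larger L1 share among the DHS they had than matched genes. L1 DHS made up 37.5% of the noncoding DHS of both stages over all genes. Against random genes matched for their number of DHS (100000 draws, two-sided permutation test), chemoreceptor genes had an L1 share of 41.9% (384 of 916 DHS, expected 35.5%, adjusted p = 3.4e-04, from the smallest p that these draws can give). F-box genes stood at 42.6% (175 of 411, expected 36.5%, adjusted p = 6.8e-04, permutation test), detoxification genes at 68 of 158 DHS (expected 34.7%, adjusted p = 0.00657) and histone genes at 47.9% (23 of 48, expected 34.5%, adjusted p = 0.0332). The homeobox genes of the ceh class were lower, at 32.4% (61 of 188, expected 38.4%, adjusted p = 0.0434, permutation test). The other 29 lists did not pass. Members of these lists still had more embryo than L1 DHS more often than the reverse, at 170 against 48 chemoreceptor, 64 against 20 F-box, 28 against 12 detoxification and 7 against 6 histone genes. Among the members with most L1 DHS, srab-24 had 7 embryo and 6 L1 DHS, srbc-40 3 and 4, srg-66 2 and 4 and srh-257 4 and 4. fbxa-148 and fbxb-22 had 4 and 5 each, fbxb-100 3 and 5, cyp-13A8 1 and 3, cyp-42A1 3 and 3, cyp-13A2 2 and 2, and ugt-65 7 and 3. his-24 had 3 and 3, and his-46, his-59 and his-63 had 1 and 2 each. In the ceh class ceh-27 had 6 and 1, ceh-13 6 and 3, ceh-43 9 and 6 and ceh-18 11 and 8. With the embryo list reduced to the L1 number by score, 1 list passed, the chemoreceptors (4.39 points above matched genes, 6.43 before), and with 1 gene kept per neighbourhood 2 lists passed, the chemoreceptor and F-box genes. The same 2 passed among genes with at least 3 DHS over both stages. Some differences stayed about as large where the call was lost. Detoxification genes went from 8.29 to 7.69 points and ceh genes from -5.99 to -4.82 with 1 gene per neighbourhood, while histone genes went from 13.5 to 6.71. With at least 3 DHS these were 6.92, -5.79 and 11.04 points. With the reduced embryo list they were 2.40, -4.71 and 3.10, and F-box genes went from 6.09 to 3.41. Within 10 groups of each chromosome in gene order, the chemoreceptor odds ratio for L1 DHS went from 1.21 (1.06 to 1.38) to 1.13 (0.983 to 1.29). The F-box one went from 1.24 (1.02 to 1.51) to 1.19 (0.977 to 1.46), so that both intervals then included 1. The histone odds ratio went from 1.54 to 1.56, the detoxification one from 1.26 to 1.23 and the ceh one from 0.8003 to 0.850, with intervals that included 1 before and after. These odds ratios set each list against all other genes. Unlike the permutation test, they were not matched for the number of DHS per gene.

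**Figure D4:**
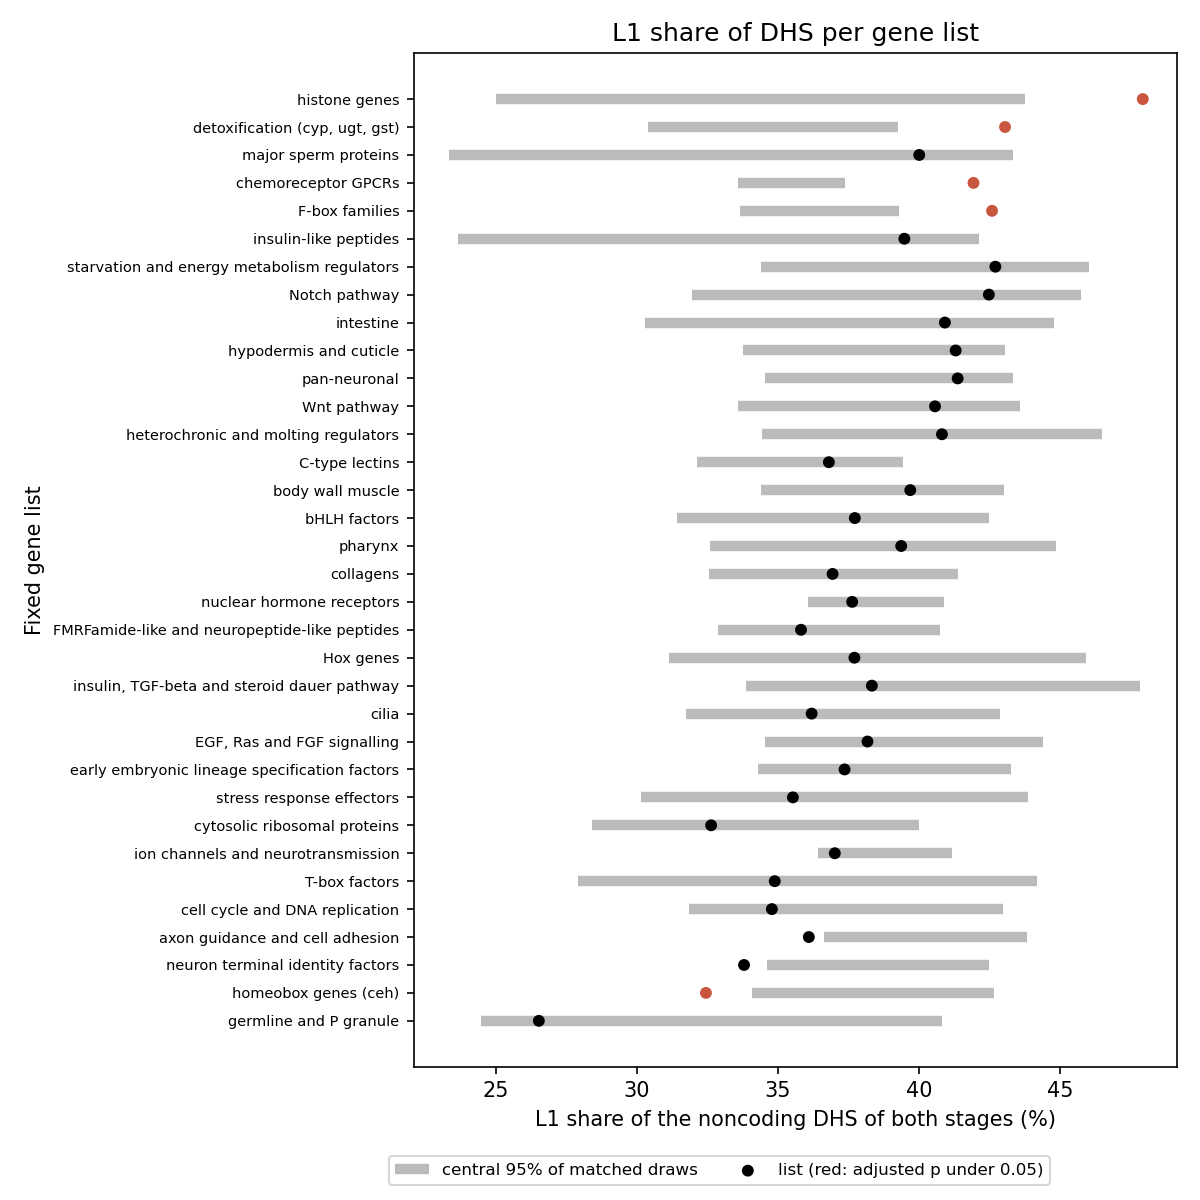
L1 share (%) of the noncoding DHS of both stages for each fixed gene list (points), with the central 95% of matched random draws as grey bars. Histone, detoxification, chemoreceptor and F-box genes lie above their bars and the ceh homeobox genes below, in red.

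No fixed list differed from other genes in the share of its L1 genes with an arrest-associated DHS (0 of 34 by Fisher's exact test, with 2 at an unadjusted p under 0.05). These were the heterochronic and molting regulators with 6 of 14 genes (p = 0.0306, adjusted p = 0.724, Fisher's exact test) and hypodermis and cuticle genes with 9 of 26 (p = 0.0426, adjusted p = 0.724). Over all genes with an L1 DHS the share was 18.5%. This test was not matched for the number of L1 DHS per gene. By DHS, 7 of 71 of the heterochronic and molting list were arrest-associated (expected 10.6% from matched genes). For hypodermis and cuticle genes it was 12 of 64 (expected 10.9%). Neither passed (adjusted p = 0.989 and 0.715, permutation test). Counted by DHS instead of genes, 69 of 384 L1 DHS of chemoreceptor genes were arrest-associated (expected 11.1%, adjusted p = 0.00204, permutation test). With 1 gene kept per neighbourhood the share was 38 of 226 DHS and did not pass (adjusted p = 0.384, unadjusted p = 0.0113, permutation test), while its difference from matched genes went from 6.89 to 5.63 points. The central 95% of matched draws ran from 8.07 to 14.3% for all genes and from 7.08 to 15.5% with 1 gene per neighbourhood.

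The region of the Hox genes lin-39 (WBGene00003024) and ceh-13 (WBGene00000437) served the authors as a control when they chose digestion levels. On chromosome III of ce10, from 7530781 to 7559990, the embryo table assigned 8 noncoding DHS to lin-39 and 6 to ceh-13, and the L1 table assigned 2 and 3. Each of the 5 L1 DHS overlapped an embryo DHS, and none was arrest-associated. Of these DHS, the one with the highest score in each stage lay at 7551621 to 7551770, in intergenic sequence 3891 bp from ceh-13. Its deposited score was 375 in the embryo and 497 in L1, scales that are not comparable between lists. The lin-39 intron held a DHS in both stages at 7535421 to 7535570. The DHS at 7536641 to 7536790, 9 bp from lin-39 and in the promoter class by this distance, was listed in the embryo alone.

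**Figure D5:**
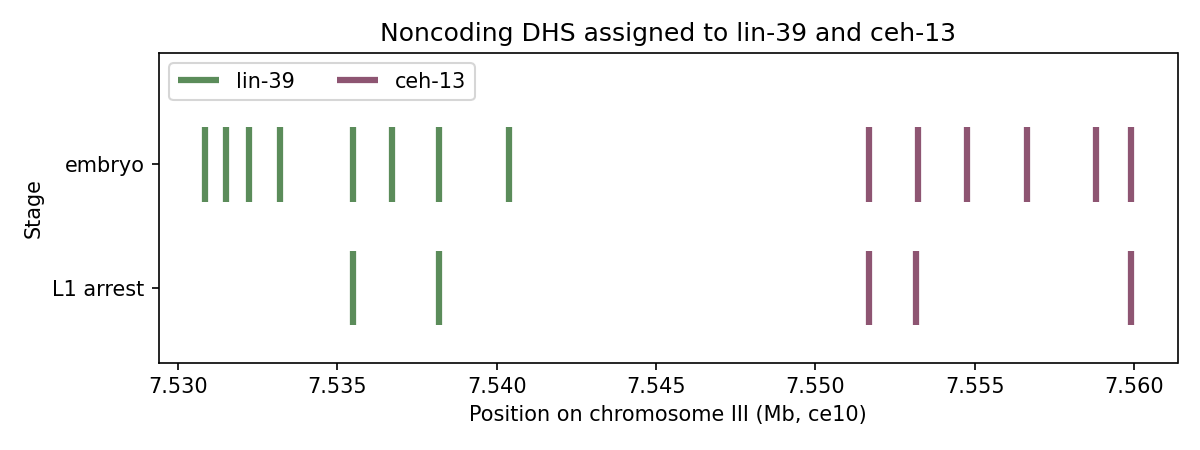
Noncoding DHS assigned to lin-39 and ceh-13 along chromosome III (position in Mb, ce10), with 1 line of marks per stage and 1 vertical line per DHS. The embryo has 14 DHS and L1 has 5, each of the 5 overlapping an embryo DHS.

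Motifs were given for the embryo alone, so no stage comparison was made. The authors' deposited motif file held 57 entries with 56 distinct words. The entry with the smallest p, GCRGCCGACA, had 232 sites against 8 in the background in the authors' file (p = 8.9e-59). It was followed in the authors' file by ACTACAAAMT in intronic DHS, with 204 against 6 sites (p = 3.0e-53), and by GCVGCCGAC, with 196 against 16 (p = 3.7e-41). In the authors' background comparison GGGNTCGAACC had 144 against 5 (p = 6.9e-37) and GDGGAGTACAC 118 against 2 (p = 4.8e-33). In the authors' deposited anatomy table, which listed 74 entries for 70 distinct pairs of a motif and a tissue, the smallest fraction of hits with similar or greater enrichment was 3.4e-04, for CGTGGYGAGAC and the germline. GCVGCCGAC was listed with vulval muscle (0.004) and with body wall musculature (0.00754). In the authors' deposited table of gene ontology terms, 456 of 1692 entries had a p-value of 0 as written.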

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

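The alternatives that split the embryo list for location and chromosome, those without the crowded window on chromosome IV, and those for overlap with any embryo DHS, for quintiles of score, for arrest-associated footprints by width and for counting DHS with 1 gene per neighbourhood were chosen after seeing the data. The share of L1 DHS overlapping an embryo DHS was 88.2% with 50% coverage, 88.1% with 50% reciprocal overlap, 88.6% for noncoding DHS, 89.3% in the higher-scoring 50% of each stage and 78.3% with the embryo list reduced to the L1 number. The share of embryo DHS was 49.9%, 49.9%, 53.5%, 50.6% and 78.3% in that order. The arrest-associated share was 10.05% when overlap with any embryo DHS was excluded. The noncoding share difference was 5.24 points for DHS of at least 200 bp and did not pass the test. For those DHS the intron difference was 15.1 points and the intergenic one -14.04, which turned their directions over 15 L1 and 19 embryo DHS. No arrest-associated DHS was that wide, so that comparison gave no value. Without X the promoter difference was -0.883 points and passed. The footprint difference turned to -1.56 points with matched widths and to -6.39 in shared DHS. The number of lists by stage shift was 2 with 1 gene per neighbourhood, 2 for genes with at least 3 DHS and 1 with the reduced embryo list. Among arrest-associated DHS counted by DHS, 1 list passed. The causes of these changes were not tested one by one. The footprint difference of arrest-associated DHS went from -12.7 to 0.510 points within bins of width and quintiles of score together. The other 39 alternative values of the main results kept their direction and, where tested, side of the threshold, or stayed within a factor of 1.5 for counts and the interval for shares. Their sizes could still change, as the number of lists with an embryo DHS went from 22 to 16 with 1 gene per neighbourhood and the arrest-associated footprint difference from -12.7 to -2.58 points within bins of width. Single lists were followed only where the main test called them, and for the chemoreceptors among arrest-associated genes. Of these, 120 alternative values kept their side of the threshold, 20 no longer passed and 1 passed newly. Other lists also passed newly and are not in this count. With 1 gene per neighbourhood, for example, 18 lists passed in L1, 16 of them also in the main test. The missing read depth limits each comparison between the stages. No paired analysis was possible because the replicate letters differ between stages.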

Other observations

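The families by name prefix, the scan of windows and the ranking of sites open in both stages are tests chosen only after results had been seen. Among name prefixes with at least 20 genes, the srh chemoreceptor genes had 16 of 65 L1 DHS arrest-associated (24.6%, 13.6 points above matched genes, adjusted p = 0.0473, permutation test), and the srw chemoreceptor genes 10 of 35, which did not pass (28.6%, adjusted p = 0.0504). These families were not thinned to 1 gene per neighbourhood, and the chemoreceptor list as a whole did not pass by DHS when it was (38 of 226, adjusted p = 0.384, permutation test). By stage shift, the fbxa genes had an L1 share of 45.6% (78 of 171 DHS, expected 37.3%, adjusted p = 0.0107, permutation test), and the cytochrome P450 genes of the cyp prefix 45.7% (32 of 70, expected 33.9%, adjusted p = 0.0222). The srw genes stood at 47.3% (35 of 74, expected 36.1%, adjusted p = 0.0222, permutation test), the his genes at 47.9% (23 of 48, expected 34.5%, adjusted p = 0.0335), and the ceh genes lower, at 32.4% (61 of 188, expected 38.4%, adjusted p = 0.0494).

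Arrest-associated DHS were fewer on X than other L1 noncoding DHS, and 3 technical explanations were tested. Within quintiles of L1 score the odds ratio for X was 0.670 (0.584 to 0.769), which argues against L1 peaks near the L1 calling threshold as the whole cause. The L1 score does not show how near the embryo signal at these sites lay to the embryo threshold, so that part was not tested. Without the 14 genes that hold 4 or more arrest-associated DHS it was 0.694 (0.603 to 0.797), and within quintiles of the number of other embryo DHS within 10 kb it was 0.728 (0.634 to 0.836). These argue against crowded autosomal neighbourhoods and against a denser embryo list on X as the whole cause. Read depth and mapping on X were not tested, and a stage difference on X stays open as a hypothesis.

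The neighbouring genes Y73B6A.1 and Y73B6A.3, chosen after their values were seen, lie with 35 arrest-associated DHS on chromosome IV from 6667081 to 6733190, where the L1 list had 73 DHS and the embryo list 40. Of the 38 sites open in both stages there, 36 ranked higher among all shared sites by L1 score than by embryo score, with a median percentile of 91.8 against 17.8, and the mean rise was 59.2 percentile points, against at most 19.9 in any run of 38 shared sites elsewhere. Such ranks go with a raised L1 signal over the whole block, beyond the arrest-associated sites. The window held 0 coding L1 DHS, so a repeat or copy number and a regulatory difference cannot be told apart. The authors removed repeats from the peaks, per the series design text, but repeats and mapping in this block could not be checked without the genome sequence.

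The gene lists that differed in the L1 share of their DHS were weighed against position along the chromosomes and against an embryo list that reaches weaker peaks. Within 10 groups per chromosome in gene order, 0 of the 5 lists had an odds ratio whose interval excluded 1, but the histone, ceh and detoxification intervals included 1 before this step as well. Unlike the permutation test, these odds ratios were not matched for the number of DHS per gene. The chemoreceptor odds ratio went from 1.21 (1.06 to 1.38) to 1.13 (0.983 to 1.29) and the F-box one from 1.24 (1.02 to 1.51) to 1.19 (0.977 to 1.46), while the histone one went from 1.54 to 1.56, the detoxification one from 1.26 to 1.23 and the ceh one from 0.8003 to 0.850. With the embryo list reduced to the L1 number by score, 1 of the 5 lists passed, the chemoreceptors (6.43 to 4.39 points, adjusted p = 0.00102, permutation test), while histone (13.5 to 3.10), detoxification (8.29 to 2.40), F-box (6.09 to 3.41) and ceh genes (-5.99 to -4.71) did not. Weaker embryo peaks cannot be told apart from a stage difference, since every difference became smaller with the reduced list but kept its direction. For position, the chemoreceptor, F-box and ceh odds ratios moved toward 1, while the histone and detoxification ones changed little. All these intervals included 1 within the groups, so position cannot be told apart from a stage difference either. The stage itself stays open.

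Within quintiles of score the odds ratio of chemoreceptor DHS for being arrest-associated was 1.81 (1.38 to 2.38), while with 1 gene kept per neighbourhood the list did not pass (adjusted p = 0.384, permutation test) at 5.63 points above matched genes. A scan of 1987 windows of 50000 bp (one-sided exact binomial test) found runs of arrest-associated DHS beyond the block on IV. On chromosome II, from 14300001 to 14350000, 8 of 10 L1 noncoding DHS were arrest-associated (adjusted p = 6.91e-04, exact test). On chromosome III the windows that start at 2800001, 13550001 and 1200001 had 5 of 6, 11 of 28 and 8 of 16. On X the window that starts at 16900001 had 8 of 16, against the lower share of X as a whole (adjusted p = 0.0448 for each of these 4, exact test).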
